A study of Homo sapiens with 2 samples.

How the data were processed

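Gene expression was measured in 2 samples of MCF10A cells, 1 control and 1 treated with black currant extract (50 µg/ml, 24 h), grouped by the agent given in the labels. Per the labels' protocols, Cy3-labelled cRNA was made from 0.1 µg of total RNA per sample with a low-input amplification kit. The deposited scanner files hold an intensity per spot. Per the file headers, the authors' arrays were read with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 10.10. Per the file headers, spatial and multiplicative detrending were on, local background correction was off, and low spots were given surrogate values. These steps act within an array, and the deposited processed intensity carries no normalization between arrays. The deposited spot flags (well above background, positive and significant, outlier, saturated) are values of 0 or 1 per the file headers. The deposited series table holds the same processed intensity on a linear scale, not centred. Among probes with a single spot 100% of its values lay within 0.01% of the scanner value, and its column medians were 30.9 for the control and 23.0 for the extract array. How it summarises repeated spots is unknown.

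Each array had 62976 spots, of which 4259 were controls. Control spots and spots flagged as outliers (371 on the control array, 325 on the extract array) were left out, and saturated spots would have been kept. The log2 of the processed signal was averaged over spots of a probe, and each array's 75th percentile over probes was subtracted. A gene's difference is the median over its probes well above background on both arrays, which gave 21790 probes and 16663 genes. Of 50596 probes, 28174 were named through an accession in a RefSeq table, 2618 through a current symbol and 620 through an older symbol, and 19184 kept the file's name. That table is of another assembly than the arrays' hg19 coordinates, so it served for names and gene types only. Exon and UTR positions of probes were not analysed here.

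With 1 array per group no test across samples was possible. Genes were counted by a rule of size, at least 2-fold. Errors come from the scanner software's error model, combined over the probes of a gene, and from repeated spots (636 repeated probes measured on both arrays). The SD between probes of a gene had a median of 0.12 over 3878 genes with at least 2 measured probes, under the median scanner error of 0.20, and was 0.33 when pooled over these genes. Of the 111 genes at least 2-fold different that had at least 2 probes, 106 had all probes on one side of 0. These genes were picked by the median of the same probes, which favours a shared side, so this count does not measure agreement between probes. For 33 gene lists and 20 families chosen before the data were examined, the median was set against 10000 random lists of the same size drawn within 20 bins of mean brightness. Its percentile describes these 2 arrays only. Named genes were, by a rule set before the data were examined, the 12 highest and 12 lowest genes with a symbol, at or above the 25th percentile of brightness, with all probes on one side of 0, up to 4 members of each list with the largest difference, up to 5 genes per direction measured on a single array with the highest bound, and a fixed set (ESR1, ESR2, GPER1, PGR, CYP1A1, CYP1B1, NQO1, HMOX1, GAPDH and ACTB). The symbols of placeholders and non-coding genes were left out of the rule of size. A gene that the rule names is not reported here.

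Alternatives planned before the data were examined were normexp background correction with an offset of 50, quantile, array median and loess normalization, no filter on dim probes, the brighter part of probes, the brightest probe per gene, the authors' series table, thresholds of 1.5-fold and 3-fold, and the positive-and-significant flag. Added after the data were seen were spike-in scaling, no scaling, removal of a smooth trend on probe GC content, genes with at least 2 probes on one side, and removal of patches. A single-spot probe lay in a patch if at least 2 neighbours within 2 rows and columns, the probe itself not counted, differed at least 4-fold in a shared direction. The probe's own value therefore did not decide its removal, and probes with repeated spots were kept.

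The slide could not be used as a block, since both arrays shared 1 slide and 1 scan. The procedure was tested on simulated data with the control array's values, the scanner errors and 200 changed genes among 16663. At simulated differences of 1.5 and -1.5, and of 3 and -3, 100% of 50 genes each passed 2-fold, and 0.0729% of the unchanged genes did. This simulation holds measurement error only and no patches, so it says nothing of false calls from either dishes or array defects. Of 200 random lists of 30 genes, 5.5% lay outside the central 95%. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.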

Results

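MCF10A is a human mammary epithelial cell line that does not form tumours. Confluent dishes of these cells were kept for 24 h in growth medium without an addition or with black currant extract at 50 µg/ml. Labelled cRNA amplified from their total RNA was hybridised to Agilent 1-colour arrays of 60-base probes. There was 1 control array and 1 extract array, so no difference below has a replicate check, no p-value is given, and "higher" and "lower" describe these 2 arrays only. Both arrays lay on 1 slide. Their place on it goes with the group and cannot be separated from it. Well above background lay 31077 of 58717 non-control spots (52.9%) on the control array and 28401 (48.4%) on the extract array. No spot was saturated. The 75th percentile of the processed signal was 653 intensity units on the control array and 522 on the extract array. Values are log2 differences, extract minus control, after each array was scaled to its 75th percentile. Errors written with ± are standard errors from the scanner software's error model and cover the measurement of the spots, not the spread between dishes. A gene's difference had a median error of 0.20, and repeated spots of a probe had a median SD of 0.061 on the control array and 0.058 on the extract array. The number of arrays limits the precision.

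The comparison asked which transcripts differed in abundance after exposure to the extract. Of 16663 genes measured on both arrays, 525 were at least 2-fold higher with extract and 390 were at least 2-fold lower, while 15748 lay within 2-fold. The lists that stood furthest from the median of all genes were those of mitosis and DNA replication, which were lower with extract, and those of luminal markers, aryl hydrocarbon receptor targets, squamous differentiation and matrix proteases, which were higher. The median over all genes was -0.01 and the SD of the differences was 0.51. The counts depended on the scaling. With the added spike-in controls as the reference, 229 genes were higher and 1520 lower (13.1% of the calls higher, against 57.4% in the main setting), and with no scaling 294 were higher and 841 lower (25.9% higher). Those scalings moved the median of all genes to -0.50 and -0.32, so the differences below are to be read relative to the median of all genes. Medians given below for other settings are relative to that setting's median of all genes. With no filter on dim probes that median was 0.22 over 36398 genes. List medians given for that setting are therefore lower by 0.22 than the members' own. They may differ from the main ones through this alone.

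**Figure D1:**
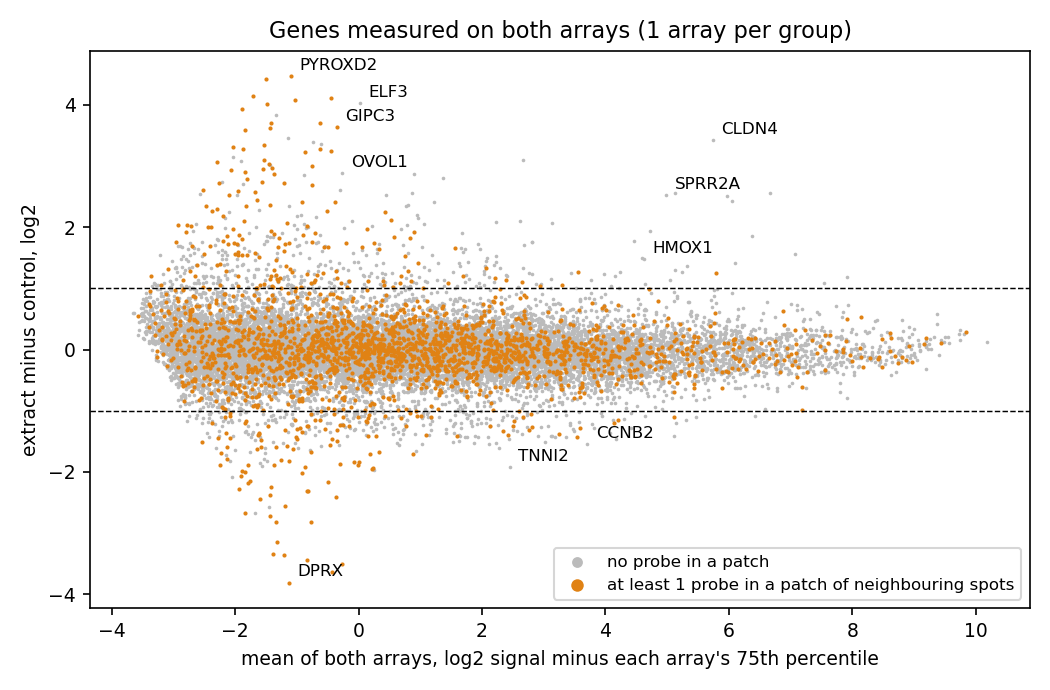
Each point is a gene measured on both arrays, with its mean normalised log2 signal on the x axis and its log2 difference (extract minus control) on the y axis. Dashed lines mark 2-fold, and orange points have at least 1 probe in a patch of neighbouring spots that differ 4-fold. ELF3 (4.03) and CLDN4 (3.42) lay outside such patches, whereas PYROXD2 (4.47), GIPC3 (3.64) and DPRX (-3.81) lay inside them.

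A part of the large differences lay in compact patches of neighbouring spots. Among single-spot probes well above background on at least one array, 1497 differed at least 4-fold. Of these, 180 were measured on both arrays. The other 1317 were well above background on a single array, so the size of their difference rests on a dim value. Of the 1497, 1064 (71.1%) had at least 2 neighbours within 2 rows and columns that differed 4-fold in a shared direction. Of the probes measured on both arrays that differed at least 4-fold, 62.8% lay in such a patch, against 10.2% of those under 2-fold. The patches covered 21.9% of single-spot probes in the first of 3 equal bands of rows, 9.85% in the middle band and 0.605% in the last band. With the 2399 probes in patches left out, an alternative chosen after the data were seen, 377 genes were at least 2-fold higher and 286 lower. Whether a named gene lay in a patch is given with it.

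**Figure D2:**
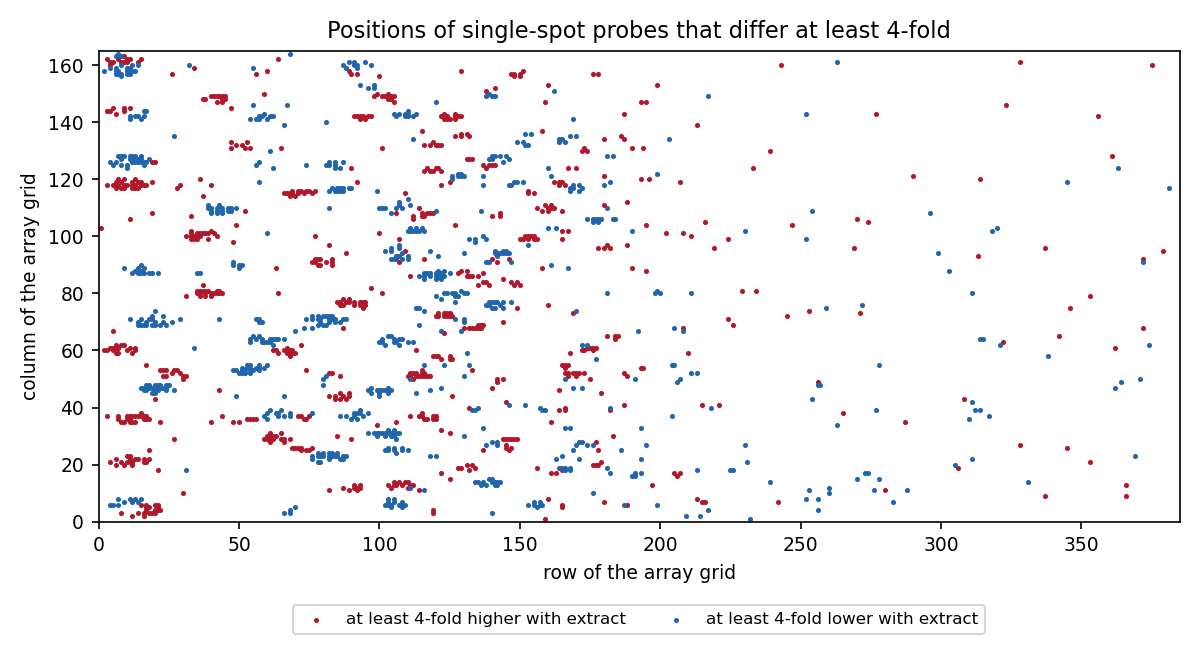
Each point is a single-spot probe that differed at least 4-fold, placed by its row (x axis, 384 rows) and column (y axis, 164 columns) on the array grid. Red points were higher with extract (744) and blue points lower (753), and most fall in compact groups of a single colour at low row numbers. Of these probes, 1317 were well above background on a single array.

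Genes of mitosis were lower with extract almost without exception. Of 33 measured members of the mitosis and G2/M list, 32 were at least 2-fold lower and none was higher, with a median of -1.31 that lay below all 10000 random lists of matched brightness. FOXM1, a transcription factor of this programme, was the remaining member at -0.88 and was chosen for mention after its value was seen. CCNB2, a cyclin of mitotic entry, had a difference of -1.54 ± 0.20, measured by a probe on chromosome 15 from 59417139 to 59417198 (hg19). CDC20, an activator of the anaphase-promoting complex, had -1.54 ± 0.20 (chromosome 1, 43826537 to 43826596). DLGAP5, a spindle protein, had -1.49 ± 0.20, and CENPA, the centromeric histone H3 variant, had -1.46 ± 0.21. None of these 4 probes lay in a patch. Of 32 measured DNA replication and G1/S genes, 18 were at least 2-fold lower and none was higher, with a median of -1.05, also below all random lists. CCNE2, the cyclin E2 gene, had -1.69 ± 0.20 over 2 probes. The replication initiation factors MCM10, CDC45 and GINS2 had -1.60 ± 0.26, -1.52 ± 0.20 and -1.44 ± 0.06. Replication-dependent histone genes had a smaller shift, with a median of -0.26 (percentile 0.18) and 1 of 26 members at least 2-fold lower. With no filter on dim probes the histone median was -0.44. H2AC13 had -1.08 ± 0.21, H3C10 -1.0 ± 0.17, H1-5 -0.89 ± 0.20 and H3C2 -0.82 ± 0.20.

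**Figure D3:**
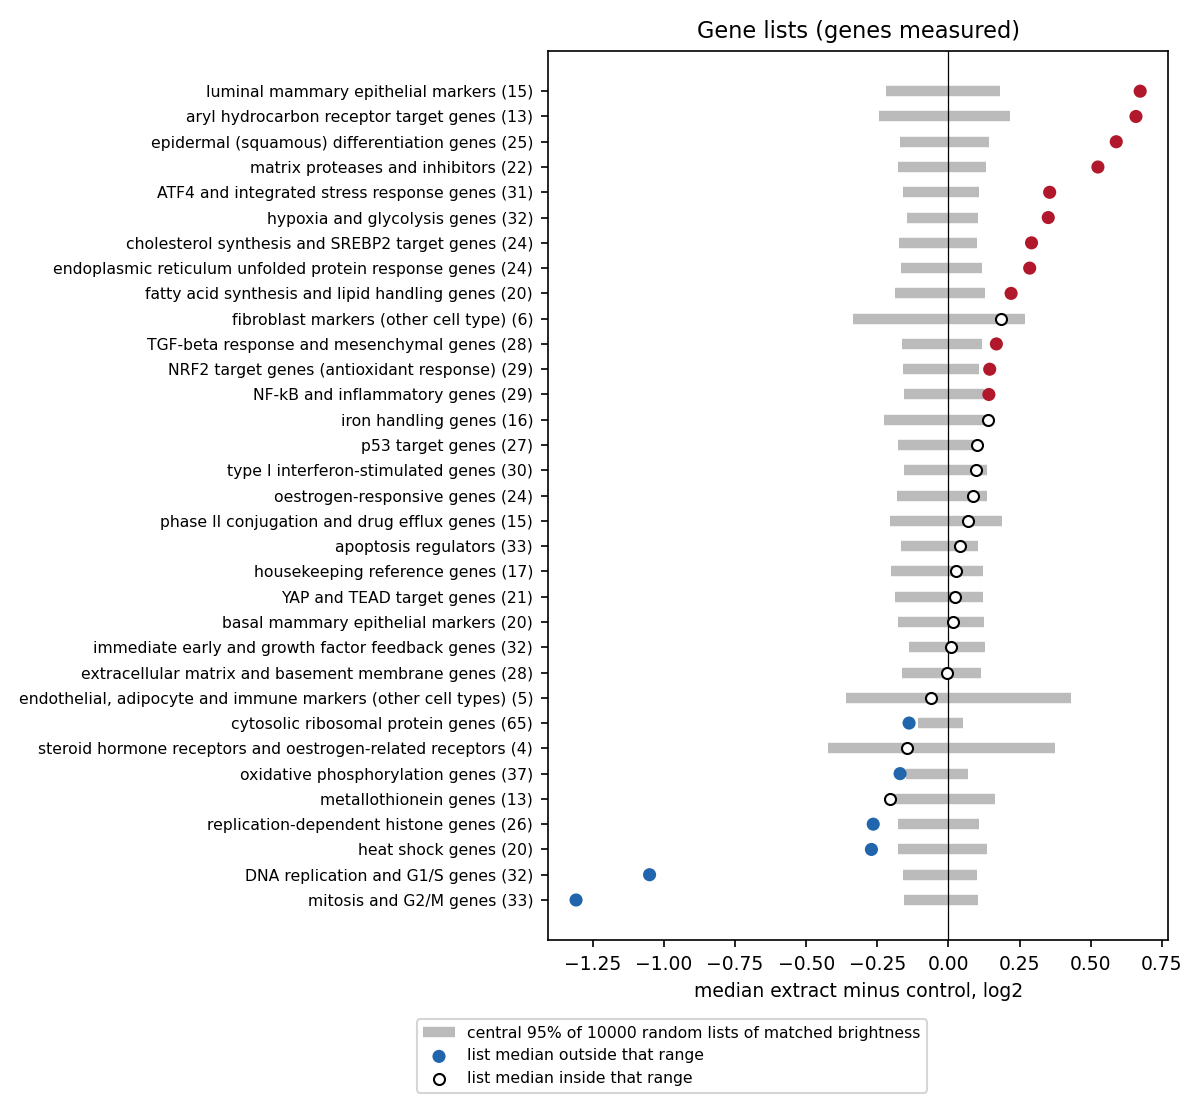
Points are the median log2 difference (extract minus control, x axis) of each gene list, with the number of genes measured in brackets, and grey bars are the central 95% of 10000 random lists of the same size and matched brightness. Filled points lie outside their bar. The mitosis list (-1.31) and the DNA replication list (-1.05) lie furthest below, and the luminal marker list (0.67) lies highest.

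Genes of squamous differentiation were higher with extract. Of 25 measured members of that list, 10 were at least 2-fold higher and none was at least 2-fold lower, and the median of 0.59 lay above all random lists (0.34 with no filter on dim probes, 1.03 in the brighter part of probes). OVOL1, a transcription factor of epidermal differentiation, had 2.89 ± 0.21 (probe on chromosome 11, 65564519 to 65564578, hg19). The cornified envelope precursors SPRR2D, SPRR2A and SPRR2F had 2.55 ± 0.14, 2.52 ± 0.14 and 2.42 ± 0.20. These genes are near-identical in sequence, so their probes may read each other's transcripts and are not independent. Of the 19 measured members other than SPRR genes, 6 were at least 2-fold higher. None of these 4 genes had a probe in a patch. Matrix proteases and inhibitors had a median of 0.53, above all random lists, with 7 of 22 members at least 2-fold higher and none lower (0.31 with no filter on dim probes). Its members with the largest differences were the kallikrein serine proteases, KLK10 with 2.85 ± 0.23, KLK5 with 2.55 ± 0.21, KLK7 with 2.34 ± 0.21 and KLK6 with 1.77 ± 0.24, all outside patches.

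Luminal mammary epithelial markers had a median of 0.67, above all random lists, with 4 of 15 members at least 2-fold higher and 1 lower (0.40 with no filter on dim probes). ELF3, an epithelial ETS transcription factor, had the largest difference among them, 4.03 ± 0.22, from 109 to 1431 intensity units (chromosome 1, 201984429 to 201984488, hg19). CLDN4, a tight junction protein, had 3.42 ± 0.20, from 7020 to 60619 intensity units (chromosome 7, 73246907 to 73246966). A second CLDN4 probe was not well above background on either array. ERBB3, a receptor tyrosine kinase, had 1.76 ± 0.16 over 2 probes that read 1.56 and 1.96. MUC1, a mucin, had 1.13 ± 0.23 over 2 probes that disagreed in size, at 0.50 and 1.76, 1 of them in a patch. Basal mammary epithelial markers had a median of 0.02 (percentile 73.2), -0.11 with no filter on dim probes and 0.13 in the brighter part of probes. Of 20 measured, 1 was at least 2-fold higher. That gene was KRT16, a keratin of activated squamous epithelium, with 1.95 ± 0.20, while DST, TP63 and CAV1 had -0.69 ± 0.12, -0.51 ± 0.29 and -0.48 ± 0.11. The 3 DST probes disagreed, at -0.70, -0.69 and 0.06.

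Targets of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds, had a median of 0.66 above all random lists, with 3 of 13 members at least 2-fold higher and 1 lower. CYP1A1, a monooxygenase induced by that receptor, had 2.69 ± 0.23 (chromosome 15, 75012562 to 75012621, hg19). Its single probe lay in a patch where 2 neighbours were 4-fold lower and 1 was 4-fold higher, so most of those neighbours went the other way. ALDH1A3, a retinal dehydrogenase, had 1.30 ± 0.20 outside patches, and CYP1B1 had 1.09 ± 0.14 over 2 probes that read 1.06 and 1.13, 1 of them in a patch. EREG, an EGF receptor ligand, had -1.13 ± 0.25. Without probes in patches the median of this list relative to all genes was 0.42 over 12 genes, and with no filter on dim probes it was 0.37.

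Targets of the antioxidant regulator NRF2 had a median of 0.14 (percentile 99.2), with 2 of 29 at least 2-fold higher. With no filter on dim probes the list's median was -0.075 relative to a median of all genes of 0.22. The members' own median therefore stayed positive. The 2 genes were FTL, the ferritin light chain, with 1.5 ± 0.12 over 3 probes, and HMOX1, haem oxygenase 1, with 1.48 ± 0.07 over 9 spots on the control array and 10 on the extract array. SQSTM1 had 0.80 ± 0.20 and AKR1C3 0.65 ± 0.20. NQO1, a quinone reductase often used as a marker of this response, had 0.16 ± 0.21, less than its error. Iron handling genes had a median of 0.14 (percentile 96.5), and 0.26 in the brighter part of probes. Of 16 measured, 3 were at least 2-fold higher, FTL, HMOX1 and the transferrin receptor TFRC with 1.13 ± 0.06. HFE had 0.83 ± 0.25. Phase II conjugation and drug efflux genes had a median of 0.07 (percentile 79.2) and none of 15 at least 2-fold different, and -0.13 with no filter on dim probes. The largest differences there were -0.76 ± 0.27 for ABCC4, whose probe lay in a patch of spots that were lower, 0.63 ± 0.23 for ABCC2, 0.41 ± 0.27 for GSTM4 and 0.35 ± 0.11 for GSTM1. Metallothionein genes, which go with metal handling, had a median of -0.21 (percentile 2.98), and -0.39 with no filter on dim probes. MT1M had -1.09 ± 0.20, MT1E -0.62 ± 0.14 and MT1H -0.37 ± 0.20, against MT1F at 1.09 ± 0.20. A second MT1H probe was not well above background on either array.

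Oestrogen receptors were poorly measured. ESR1 had -1.11 ± 0.21 from 1 of its 3 probes, and that probe lay in a patch where 2 neighbours were 4-fold lower and 1 was 4-fold higher. Its other 2 probes were not well above background on either array. ESR2 and PGR, the progesterone receptor gene, were not well above background on either array. GPER1, a membrane oestrogen receptor, had 0.72 ± 0.11 over 4 probes that read 0.33 to 0.84. ESRRA had -0.01 ± 0.14, with its sign turned under quantile and loess normalization, and NR3C1, the glucocorticoid receptor gene, had -0.29 ± 0.15 over 3 probes that read -0.57, -0.29 and -0.08, the first of them in a patch of spots that were higher. The receptor list had a median of -0.15 (percentile 23.8) over 4 genes, and 0.41 relative to all genes with no filter on dim probes. That setting adds members such as PGR, whose probes were not well above background on either array yet read 0.63. The 0.41 is therefore no measure of the receptors' abundance. Oestrogen-responsive genes had a median of 0.09 (percentile 90.8), with 2 of 24 at least 2-fold higher, KRT13 with 2.03 ± 0.21 and PKIB with 1.57 ± 0.21, and AREG and MYB at -0.97 ± 0.14 and -0.71 ± 0.24. Without probes in patches this list's percentile was 97.8, past the central 95%. With no filter on dim probes its median was -0.056 relative to a median of all genes of 0.22.

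**Figure D4:**
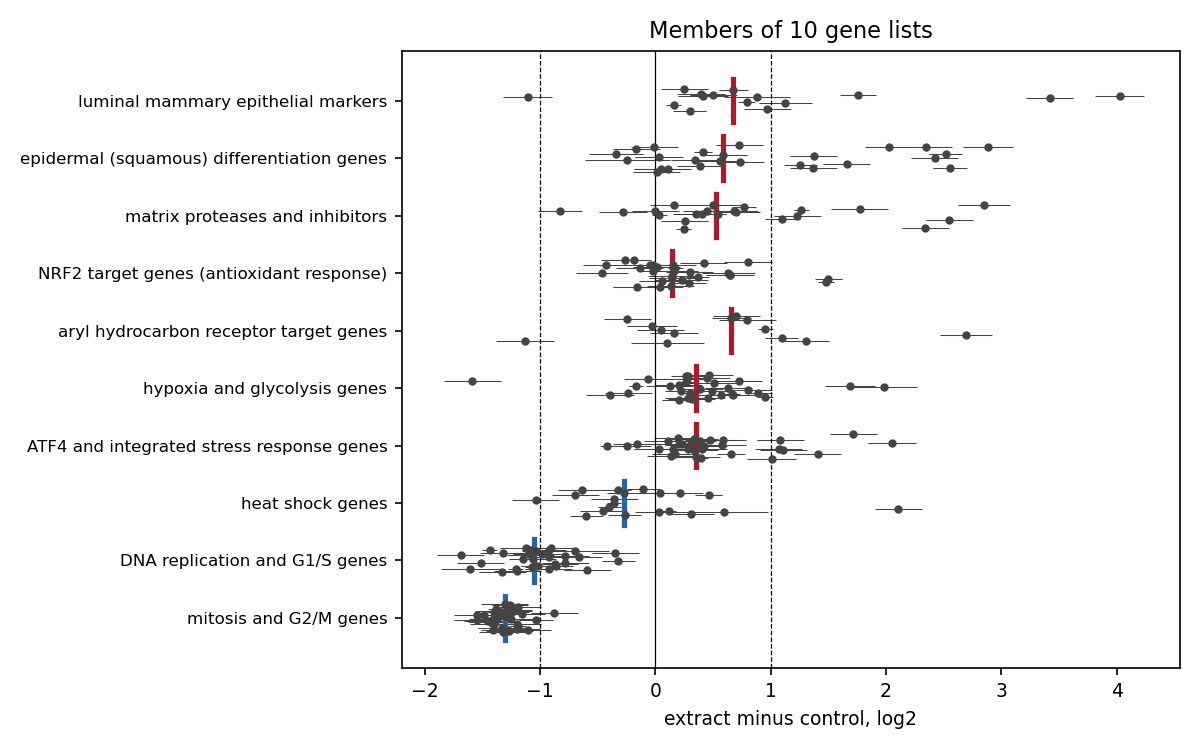
Each point is a gene of the list named on the y axis, with its log2 difference (extract minus control) on the x axis and the scanner software's standard error as a horizontal bar. Coloured lines are list medians and dashed lines mark 2-fold. The mitosis members lie close together around -1.31, whereas the luminal markers run from -1.11 (ESR1) to 4.03 (ELF3).

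Several stress and metabolic lists were higher by less. With no filter on dim probes the ATF4, unfolded protein response, hypoxia, cholesterol and fatty acid lists had medians of 0.14, 0.12, 0.17, 0.083 and 0.069. These are relative to a median of all genes of 0.22 in that setting, so they do not show smaller differences of the members themselves. ATF4 and integrated stress response genes had a median of 0.36, above all random lists, with 7 of 31 at least 2-fold higher and none lower. CHAC1, a glutathione-degrading enzyme, had 2.05 ± 0.20, CBS, a transsulfuration enzyme, 1.72 ± 0.20, NUPR1 1.41 ± 0.20 and PPP1R15A 1.11 ± 0.20. Genes of the endoplasmic reticulum unfolded protein response had a median of 0.29 (percentile 99.99) with none of 24 at least 2-fold different. HERPUD1 had 0.88 ± 0.20, ERO1A 0.67 ± 0.06, DNAJB9 0.56 ± 0.20 and HSPA5 0.54 ± 0.20. Hypoxia and glycolysis genes had a median of 0.35, above all random lists, with CA9, a carbonic anhydrase, at 1.98 ± 0.29 and ENO2 at 1.69 ± 0.22. CA9 was dim, at 49 intensity units on the control array and 155 on the extract array. LOX, a matrix crosslinking enzyme of that list, had 0.95 ± 0.07, and EGLN3 had -1.59 ± 0.25 from a probe in a patch, with its other probe not well above background on either array. Cholesterol synthesis genes had a median of 0.29, above all random lists, and none of 24 was at least 2-fold different. Its largest differences were 0.80 ± 0.07 for TM7SF2 and 0.73 ± 0.20, 0.68 ± 0.20 and 0.53 ± 0.20 for MVD, INSIG1 and FDPS, whose probes lay in patches. Fatty acid synthesis and lipid handling genes had a median of 0.22 (percentile 99.9), with ACSS2 at 0.84 ± 0.20, PNPLA3 at 0.61 ± 0.20, ACSL1 at 0.61 ± 0.06 and PNPLA2 at 0.52 ± 0.14. Heat shock genes had a median of -0.27 (percentile 0.05), but their members went both ways, with HSPA4L at -1.04 ± 0.21, HSPD1 at -0.70 ± 0.20 and HSPA6 at -0.64 ± 0.20 against the small heat shock protein CRYAB at 2.11 ± 0.20. The 2 HSPA6 probes disagreed, at -1.30 and 0.03, and with the brightest probe per gene the list's median was -0.11. Oxidative phosphorylation genes had a median of -0.17 (percentile 1.06), with CYC1 at -0.47 ± 0.20. Cytosolic ribosomal protein genes had a median of -0.14 (percentile 0.18), and 1 of 65 was at least 2-fold lower. That gene, RPS23, had -1.14 ± 0.15 from probes at -2.12 and -0.17, 1 of which lay in a patch. With no filter on dim probes the medians of these last 2 lists were -0.41 and -0.36.

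Among signalling lists, NF-kB and inflammatory genes had a median of 0.14 (percentile 98.4), which was 0.076 with normexp background correction. It was -0.064 with no filter on dim probes, relative to a median of all genes of 0.22 in that setting. Of 29 measured members, 18 lay above the median of all genes and 11 below it, such as CXCL3 at -0.71. The largest differences were CCL5 at 1.69 ± 0.35, LIF at 1.64 ± 0.20, SAA2 at 1.06 ± 0.17 and TNF at 1.03 ± 0.22. CCL5 was dim, at 32 intensity units on the control array and 84 on the extract array. The lowest signals well above background there were 26 and 33. TGF-beta response and mesenchymal genes had a median of 0.17 (percentile 99.7), and -0.050 with no filter on dim probes, again relative to 0.22. Members included SNAI1 at 1.36 ± 0.23, MMP9 at 1.26 ± 0.06, ITGB6 at 0.85 ± 0.20 and SKIL at 0.77 ± 0.21. Type I interferon-stimulated genes had a median of 0.10 (percentile 91.9), inside the random range, while 5 of 30 were at least 2-fold higher and 2 lower. ISG20 had 1.77 ± 0.20, RSAD2 1.32 ± 0.25 and IFIT1 1.23 ± 0.20, against IFI44 at -1.42 ± 0.20. Targets of p53 had a median of 0.10 (percentile 95.7), and none of 27 was at least 2-fold different. TP53INP1 had 0.76 ± 0.17, CDKN1A, a cyclin-dependent kinase inhibitor, 0.74 ± 0.20, BBC3 0.71 ± 0.20 and GADD45A 0.69 ± 0.20. Apoptosis regulators had a median of 0.04 (percentile 85.1), with HRK at 1.20 ± 0.21 and BIRC5, which also serves in mitosis, at -1.42 ± 0.06. Immediate early genes had a median of 0.01 (percentile 59.0), with FOSB at 1.45 ± 0.33, KLF2 at 1.02 ± 0.07 and the EGF receptor ligands EREG and AREG at -1.13 ± 0.25 and -0.97 ± 0.14. FOSB was dim, at 38 intensity units on the control array and 84 on the extract array. YAP and TEAD targets had a median of 0.02 (percentile 75.8), with FJX1 at -1.14 ± 0.20 and ANKRD1 at 1.12 ± 0.21, the latter in a patch of spots that were higher. Extracellular matrix and basement membrane genes had a median of -0.01 (percentile 59.99), with COL1A1 at 1.10 ± 0.20 and COL8A1 at -0.78 ± 0.20. With no filter on dim probes the interferon, p53, apoptosis, immediate early, YAP and matrix lists had medians of -0.12, -0.12, -0.15, -0.14, -0.19 and -0.14.

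Lists of other cell types lay inside the random range. Fibroblast markers had a median of 0.18 (percentile 92.4, 6 genes). Endothelial, adipocyte and immune markers had -0.06 (percentile 33.0, 5 genes), with CSF1R at 1.23 ± 0.07. The sign of the latter median turned in the brighter part of probes (0.85) and with no filter on dim probes (0.35). Having no filter adds members not well above background. Housekeeping reference genes had a median of 0.03 (percentile 79.6), and -0.19 with no filter on dim probes. GAPDH had 0.27 ± 0.06 and ACTB 0.22 ± 0.11. HPRT1 had -0.78 ± 0.20. In all, 18 of the 33 lists lay outside the central 95% of their random lists, against 1.65 expected if genes within a list varied independently. Random lists drew genes singly, so where members of a list vary together this excess cannot be read as beyond chance.

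By the rule of size, 12 genes per direction were named. Of the 12 highest, 7 lay outside patches, ELF3, CLDN4 and OVOL1 as above, PRR15L with 3.46 ± 0.08, GPR37L1 with 3.39 ± 0.24, NFE2 with 3.36 ± 0.23 and COXFA4L3 with 3.09 ± 0.20. The other 5, PYROXD2 (4.47), GIPC3 (3.64), SERPINI1 (3.28), ACSF2 (3.23) and THNSL1 (2.99), each rested on a single probe inside a patch of spots that were higher, and a second GIPC3 probe was not well above background on either array. Of the 12 lowest, only PIF1, a DNA helicase, with -1.96 ± 0.21 and TNNI2, a troponin subunit, with -1.92 ± 0.20 lay outside patches. The remaining 10, among them DPRX, CAPS2, CHIC1, CCDC122, SPMIP6, PCDH9, HECTD2, LDHC and PPP6R1, had differences from -3.81 (DPRX) to -1.83 (PPP6R1) inside patches of spots that were lower, and other probes of CAPS2, PCDH9 and HECTD2 were not well above background on either array.

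Probes well above background on a single array numbered 812 on the extract array and 3270 on the control array. Outside patches these were 330 and 2506. The lowest scaled log2 signal among probes well above background was -3.46 on the extract array and -4.23 on the control array. The counts thus rest on unlike limits of detection. Genes measured on the extract array only numbered 648, of which 604 were at least 2-fold higher by their bound. On the control array only they numbered 2361, of which 471 were at least 2-fold lower. The 10 genes with the highest bounds all lay in patches. Their bounds therefore describe the signal of a probe on these arrays and are not a least change of the gene's transcript. The NCKAP5 probe read at least 52.0-fold higher with extract, as it was not well above background on the control array. It was followed by those of STUM, SLC4A8, HSFY2 and CRYBB1. The KLHL38 probe read at least 30.4-fold lower with extract, where it was not well above background, followed by those of KCNJ12, SLC5A11, SPATA31D3 and ARMC3. The other probes of NCKAP5, STUM, SLC4A8, HSFY2 and ARMC3 were not well above background on either array, so for each of these genes the bound rests on 1 of its probes. A bound sets the bright array's value against the higher of the dim probe's own value and the lowest signal among probes well above background on that array.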

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

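The tests of other genes of like brightness, of SPRR genes, of luminal genes and of patches in the gene lists were chosen only after the related result was seen; the tests of probe GC content were added after the data were seen, but, like those of agreement between probes and of neighbouring spots, before their own result was. The added E1A spike-in controls, which the main comparison does not use, were brighter on the extract array by a median log2 difference of 0.180 (0.03 to 0.22 over 7 controls well above background), whereas the 75th percentile of the cell RNA signal differed by -0.31.

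Large differences of single spots may in good part be defects of the arrays. Among probes measured on both arrays, neighbouring pairs of 4-fold probes were 8.625 times as frequent as after shuffling positions (53 pairs against a mean of 6.14, with 2 to 11 as the central 95% of 1000 shuffles). Of 48 genes with a 4-fold probe and other measured probes, 25% had all other probes at least 1.5-fold different the same way. Both values are what an array or probe artefact needs, and unrelated genes placed at random on the grid have no reason to differ together by position. Which array carries each patch, and what made it, was not tested, and large differences outside patches stay open.

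The lower mitosis and DNA replication genes are not accounted for by the technical explanations that could be tested. The mitosis list's median relative to all genes was -1.29 after removal of the trend on probe GC content and -1.32 without patches. A smaller amount of labelled cell RNA would lower other genes of like brightness as much. With spike-in scaling, which is not centred on the cell RNA, such genes had a median of -0.51 (central 95% of random lists -0.64 to -0.38) against -1.80 for the mitosis list. That scaling shifts every gene by a constant, so this gap repeats that of the main setting and is not separate evidence. It shows only that a shift shared by such genes does not cover the mitosis list. With 1 sample per group, a difference between dishes, such as in how long they had been confluent, cannot be told apart from the extract.

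The higher squamous differentiation genes remained higher in the tests of GC content and of patches. The list's median relative to all genes was 0.65 after the GC correction and 0.74 without patches, and 6 members were at least 2-fold higher without the near-identical SPRR genes. Cells of luminal type in the treated dish are left open. KRT7, KRT8, KRT18, KRT19 and EPCAM, chosen as abundant luminal genes, had a median of 0.67 (0.25 to 0.97). All 5 were higher, though by less than CLDN4 (3.42), and how bright they read in luminal cells was not measured here. A difference between dishes stays open here as well, since there was 1 per group.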

How the results depend on the processing

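Spike-in scaling, no scaling, the GC correction, the rule of 2 probes and the removal of patches were chosen after the data were seen. No paired analysis was possible because each group had 1 sample. Relative to the median of all genes, 246 of 297 list medians under alternatives moved by less than 1 SD of random-list medians; quantile, loess and the authors' series table moved none of the 33 lists further. Array median, spike-in and no scaling shift every gene by a constant, cannot move these medians and are not counted here. Of 1258 values of named genes under alternatives, 41 fell below 2-fold, 92 moved by more than their error and none of the genes at least 2-fold different changed sign. Dim signal is the limit of depth here, with 52.9% and 48.4% of spots well above background.

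Genes at least 2-fold higher and lower numbered 525 and 390. They numbered 285 and 229 with normexp, 1993 and 1760 with no filter on dim probes, 140 and 154 in the brighter part of probes, 229 and 1520 with spike-in scaling, 294 and 841 with no scaling, 1303 and 1188 at 1.5-fold, 199 and 69 at 3-fold, and 57 and 49 with at least 2 probes on one side. The filters, the thresholds and the rule of 2 probes change which genes or sizes count; for normexp the cause was not tested, and the scalings shift all genes. Probes on the extract array only numbered 812, with the positive-and-significant flag 1609 and without patches 330. On the control array only they numbered 3270, with that flag 5511.

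Of the 18 lists outside the central 95%, 3 turned sign relative to all genes, each with no filter on dim probes, NRF2 target genes (antioxidant response) -0.075, NF-kB and inflammatory genes -0.064, TGF-beta response and mesenchymal genes -0.050. Of the lists inside it, 12 moved to the other sign with no filter, oestrogen-responsive genes -0.056, steroid hormone receptors and oestrogen-related receptors 0.41, type I interferon-stimulated genes -0.12, p53 target genes -0.12, extracellular matrix and basement membrane genes -0.14, basal mammary epithelial markers -0.11, immediate early and growth factor feedback genes -0.14, YAP and TEAD target genes -0.19, phase II conjugation and drug efflux genes -0.13, apoptosis regulators -0.15, endothelial, adipocyte and immune markers (other cell types) 0.35, housekeeping reference genes -0.19. In the brighter part of probes 1 did so, the endothelial, adipocyte and immune markers. Further lists inside it took the other sign while moving by less than 1 SD, 7 with normexp, 4 without patches, 3 with loess and 2 in the brighter part of probes. With no filter on dim probes, lists that moved and kept their sign were aryl hydrocarbon receptor target genes 0.37, mitosis and G2/M genes -1.53, DNA replication and G1/S genes -1.28, ATF4 and integrated stress response genes 0.14, endoplasmic reticulum unfolded protein response genes 0.12, hypoxia and glycolysis genes 0.17, cholesterol synthesis and SREBP2 target genes 0.083, fatty acid synthesis and lipid handling genes 0.069, matrix proteases and inhibitors 0.31, epidermal (squamous) differentiation genes 0.34, luminal mammary epithelial markers 0.40, metallothionein genes -0.39, cytosolic ribosomal protein genes -0.36, oxidative phosphorylation genes -0.41, replication-dependent histone genes -0.44. With normexp, lists that moved were aryl hydrocarbon receptor target genes 0.46, NF-kB and inflammatory genes 0.076, ATF4 and integrated stress response genes 0.30, matrix proteases and inhibitors 0.42, luminal mammary epithelial markers 0.51, cytosolic ribosomal protein genes -0.19, oxidative phosphorylation genes -0.23. In the brighter part of probes they were DNA replication and G1/S genes -0.97, epidermal (squamous) differentiation genes 1.03, basal mammary epithelial markers 0.13, luminal mammary epithelial markers 0.55, iron handling genes 0.26, endothelial, adipocyte and immune markers (other cell types) 0.85. With the brightest probe they were heat shock genes -0.11, hypoxia and glycolysis genes 0.44, luminal mammary epithelial markers 0.80. With the GC correction they were DNA replication and G1/S genes -0.96, hypoxia and glycolysis genes 0.44, extracellular matrix and basement membrane genes 0.096. Without patches they were aryl hydrocarbon receptor target genes 0.42, epidermal (squamous) differentiation genes 0.74. With no filter on dim probes the reference itself moved, to a median of all genes of 0.22 against -0.01 in the main setting. A list there can move or take the other sign with its members' own median unchanged. Other causes were not tested for these lists, except that the filters change which genes are measured.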

Other observations

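Among gene families taken by symbol, SPRR genes had a median of 2.47 with 6 of 8 at least 2-fold higher, and kallikrein (KLK) genes 2.34 with 5 of 7, both above all random lists. Keratin genes had a median of 0.31, also above all random lists, with 4 of 28 at least 2-fold higher and 1 lower. SERPINB genes had 0.42 (percentile 99.9), with 0 of 7 at least 2-fold higher. Genes with symbols starting ITGA or ITGB had 0.26 (percentile 99.9), with 1 of 21 at least 2-fold higher. Taken by symbol, that set is not limited to integrins, and its lowest member was ITGB3BP at -0.69. ADAMTS genes had 0.42 (percentile 98.7) and solute carriers 0.06 relative to all genes (percentile 98.4, 229 genes). Ribosomal protein genes by symbol had -0.14 (percentile 0.06) and MT genes -0.25 (percentile 2.21).

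Of the families, 9 of 20 lay outside the central 95% of random lists. ZNF (percentile 20.1, 381 genes), COL (30.4), LAM (27.9), FZD (78.8), IGFBP (75.2), KRTAP (88.9), CLDN (92.9), WNT (93.8), HLA (94.9), S100 (96.4) and olfactory receptor genes (96.7) lay inside. The olfactory receptor and KRTAP families held 3 of 23 and 4 of 32 genes at least 2-fold higher.

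The repeated probes, averaged over about 10 spots, give the most precise differences. Of 636 such probes, 16 were at least 2-fold higher and 24 at least 2-fold lower.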
